A study of Mus musculus with 2 samples.

How the data were processed

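ATAC-seq of mouse Th2 cells was deposited as 1 list of open regions per library, for 2 libraries of 1 group. The labels give them as biological replicates 1 and 2, from separate biosamples of the same donor record, and do not state sex or age. Nothing says that they came from separate animals, so the spread between them may be technical. There was no control, treatment or second cell type, and reads, alignments and signal tracks were not analysed here.

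Per the file headers, each list was derived by the authors from 1 alignment of the same library on mm10, so regions were called per library and not on pooled reads. The region names carry words for masking, removal of duplicates and sorting. They also carry the words ASTARR and insert and a time in hours, which no source used here explains. If these mean that fragments of a cloned library were sequenced, the fold enrichments would measure its inserts. The aligner, the peak caller, the shift applied for the transposase and the software versions are not given in the sources used here. Each region has a start, an end, a summit and the authors' fold enrichment, read here as a ratio of the count at the summit to local background. The deposited −log10 p-value and −log10 q-value of each region are the authors' own, and the lowest −log10 q in the lists was 1.00 and 1.01. The deposited score is 10 times −log10 q, capped at 1000 (99.99% of regions in both lists), and was not used further. Fold enrichments were used to describe and rank regions within a list.

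The depth of the libraries is not stated. The fold enrichment and p-value of each region together fix the pileup, or count at the summit, and background, if both follow a Poisson model with a pseudocount of 1. The sources used here do not state whether the pileup counts fragments, reads or cut sites. Whole-number pileups that return the deposited p within 0.001 of −log10 p were found for 51555 of 51557 regions of replicate 1 and 60885 of 60891 of replicate 2. Pileups moved by 0.5 counts met this tolerance for 0% of regions, which follows from the narrow tolerance and is no separate support for the model. Median summit pileups were 31 (25th to 75th percentile 18 to 64) and 37 (21 to 78), and the genome-wide background coverage was 2.90 and 3.43, a ratio of 1.18. Intervals and pileups cover counting error only.

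No regions within a list overlapped or touched, so merging changed none. A region was shared when it overlapped a region of the other replicate by at least 1 bp, and overlapping regions of both were joined into shared regions. The expected overlap came from 100 circular shifts of replicate 2's list along each chromosome. The genome was GRCm38 with the GENCODE M21 basic annotation, the build of the lists, and on 0 chromosomes did a region end past the chromosome. Regions were classed by their centres, in the order promoter (within 1 kb of any annotated start site of a protein-coding gene), exon, intron and intergenic, on 21 main chromosomes. Only protein-coding genes were used, so an intergenic region can lie in a gene of another kind.

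The 17 gene lists were Th2, Th1, Th17, regulatory, follicular helper, naive and memory, pan-T cell, activation, antigen receptor with AP-1, NFAT and NF-κB, JAK and STAT, CD8 and natural killer cell, B cell, myeloid, mast cell and basophil, erythroid and megakaryocyte, non-haematopoietic and housekeeping genes. Of 236 symbols 235 matched the annotation, and Clec7a did not. Lists, consensus sequences, tests, alternatives and the rule for named genes were fixed before the data were examined. Promoter shares were compared with all other protein-coding genes by Fisher's exact test. The median number of shared regions in the gene body and 20 kb on each side was compared with 10000 random lists matched on gene length in 20 bins. The Th2 list was set against 4 helper lists with 100000 permutations of genes. Consensus sequences (30) were searched on both strands in 200 bp windows at summits and in windows of the same width 1 kb away that overlapped no region. Tests were two-sided except the shifts, and p-values were adjusted by Benjamini-Hochberg within each family. Regions and genes are not independent replicates, so these p-values describe this group's lists and not a population of animals. For clusters, shared regions outside promoters within 12.5 kb were stitched and ranked on summed fold enrichment.

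Named genes were every Th2 list member and, of each other list, the 3 with most and the 2 with fewest shared regions, and those without a promoter region where there were fewer than 5. The rule named no way to break ties, and tied genes were all taken. Some genes that the rule takes are not reported here. Every region from Kif3a to Il5, the genes at the 15 highest clusters, at the 10 strongest promoter and 10 strongest other regions, and at the 5 strongest regions of 1 replicate alone were also named. Outside this rule, Tbx21, Il17a, Il17f, Cd8b1, Blnk, Socs1, Ppp1r3f and Ccdc22 were chosen after their values were seen.

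Alternatives were −log10 q of at least 10, reciprocal overlap of 50%, summits within 100 bp, joining within 150 bp, lists of equal length, −log10 p in place of fold enrichment, promoters of 2.5 kb or the gene's 5′ end alone, the gene body alone or with 100 kb, the strongest region's rank in place of the number, windows of 100 bp, control windows matched on G and C content, reversed consensus sequences, a stitching distance of 5 kb, ranking by the number of regions, and each replicate alone.

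The tests were tested on simulated data. A list shifted at random overlapped by 2.88% (2.67% by shifts, permutation p = 0.0952) and one with part of its regions kept in place by 50.7% (51.4% set). Of 200 random lists of 15 genes, 2% passed p under 0.05 for the number of regions and 2.5% for the promoter share. Lists drawn from the genes with most regions passed in 70.5%, and lists of genes with a promoter region in 100%. Of 100 random pairs of lists, 0% passed in the test between lists, and no pairs with a true difference were simulated for it. AP-1 sites planted in 20.6% of 5000 windows were found in 22.5%, against 2.44% of control windows. Of the 26 sequences without the AP-1 core, 0 passed. Both sets of simulated windows had the same base content, unlike summits and flanks, so differences in base content were not simulated. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Regions on unplaced scaffolds and the mitochondrial chromosome were left out of the comparisons that use the annotation.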

Results

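Open chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in mouse T helper 2 (Th2) cells. Th2 cells are the CD4 T cells that secrete the type 2 cytokines Il4, Il5 and Il13. The cells were primary cells of the strain C57BL/6NJ, and the labels give 1 group of 2 biological replicates with no control or second condition. The design therefore implies a comparison of the replicates and a description of the regions open in both. Replicate 1 held 51557 open regions covering 34.0 Mb, or 1.25% of the chromosomes, with a median width of 534 bp. Replicate 2 held 60891 regions covering 38.6 Mb, or 1.41%, with a median width of 509 bp. The median fold enrichment over background, the authors' value at each region's summit, was 5.58 in replicate 1 and 5.65 in replicate 2. The median summit pileup recovered from the deposited values was 31 counts in replicate 1 and 37 in replicate 2. Words in the region names leave open whether the sequenced fragments came directly from the cells or through a cloned library, and the fold enrichments are read here as the labels give the assay. All coordinates are on mm10.

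The type 2 cytokine locus on chromosome 11 held 18 separate regions open in both replicates, from the Kif3a promoter to the Il5 promoter. None lay between 53663743 and 53706554 within Rad50 or between 53567954 and 53589491 within Kif3a. Values are given as fold enrichment in replicate 1 and then replicate 2. At Il4, the cytokine that drives Th2 differentiation, the promoter region lay at 53616723 to 53618024 with 7.42 and 6.94, and a region in intron 1 at 53614587 to 53615532 had 2.48 and 2.98. The strongest region near Il4 outside promoters lay 3′ of its annotated protein-coding transcripts, 11.9 kb downstream of the start site, at 53604653 to 53606294, with 10.1 and 11.5. At Il13, which drives mucus production and airway reactivity, a region over exon 1 at 53634442 to 53634771 had 2.60 and 2.76. A second Il13 region, centred 1.473 kb upstream at 53635656 to 53636694, had 3.99 and 5.60. The regions at 53626815 to 53628144 and 53630095 to 53630667, both intergenic between Il4 and Il13, had 5.83 and 5.05, and 2.36 and 2.34. The Il5 promoter region at 53719455 to 53720283, 925 bp upstream of the start of this eosinophil growth factor, had 8.20 and 9.13.

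The DNA repair gene Rad50, whose 3′ part holds the locus control region of the type 2 cytokines, carried 4 shared intronic regions. They lay in intron 24 at 53650817 to 53651621 with fold enrichments of 6.76 and 8.10, and in intron 22 at 53654733 to 53655553 with 6.55 and 6.65. The remaining 2 lay in intron 21, at 53656563 to 53657332 with 8.86 and 8.11 and at 53662743 to 53663743 with 6.85 and 9.27. The Rad50 promoter region at 53706554 to 53708140 had 10.7 and 10.1. Between Rad50 and Il5, the regions at 53713591 to 53714271 and 53716623 to 53717056 had 6.78 and 6.997, and 3.76 and 4.97. The Kif3a promoter at 53566913 to 53567954 had 14.0 and 15.7, the highest values of the locus. Introns 9 and 10 of Kif3a held regions at 53589491 to 53591051 with 6.14 and 6.72 and at 53592313 to 53593402 with 5.00 and 4.93.

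**Figure D1:**
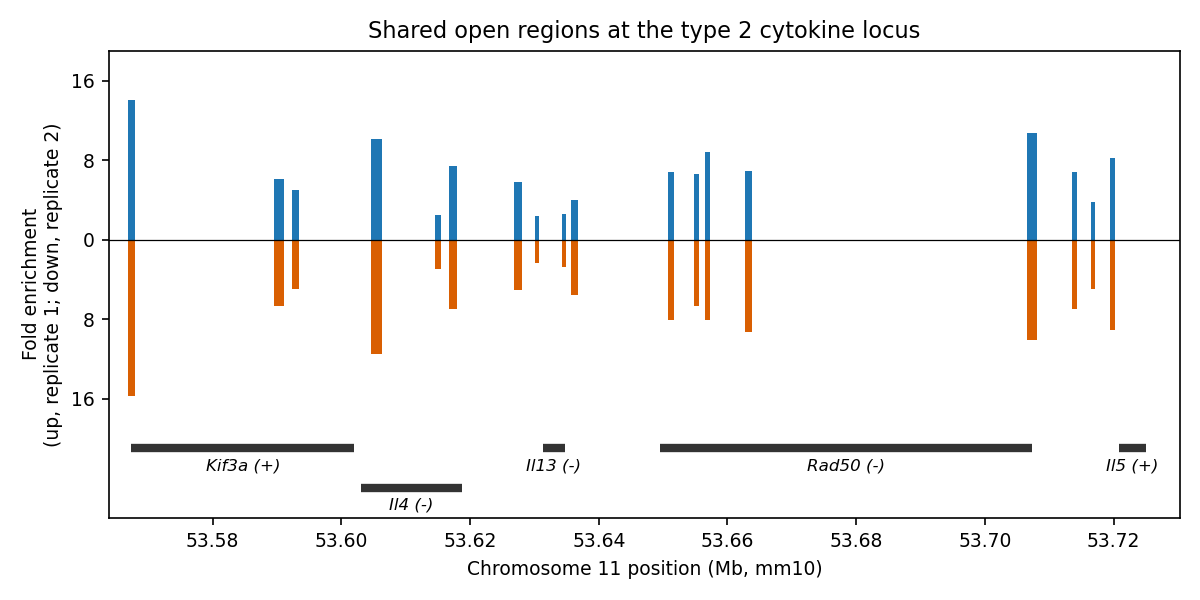
Shared open regions at the type 2 cytokine locus. The x axis is the position on chromosome 11 in Mb (mm10), bars give the fold enrichment of each of the 18 regions, upward for replicate 1 and downward for replicate 2, and dark lines mark the annotated gene spans with their strands; the Kif3a promoter reached 14.0 and 15.7 and the Il5 promoter 8.20 and 9.13.

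Of the 18 genes of the Th2 list, 15 (83.3%) had a shared region within 1 kb of a transcription start site, against 58.1% of other protein-coding genes. This passed the test (Fisher's exact test, two-sided, p = 0.0319, adjusted p = 0.0492 over 17 lists). With the gene's 5′ end as the only start site the share was 72.2% (adjusted p = 0.249, exact test), and with replicate 1 alone it was 83.3% (adjusted p = 0.0739), so the call was lost in both. The 3 genes without a promoter region were Il10, Il1rl1 and Ptgdr2, the last 2 encoding the receptors ST2 and CRTH2. The median Th2 gene had 6 shared regions in its body and 20 kb on each side, against 2 in random lists matched on gene length (permutation p = 0.0002, the smallest that 10000 lists can give, adjusted p = 0.00068). When each gene was scored instead by the rank of its strongest region, the list did not pass (permutation test, adjusted p = 0.81), and neither did any of the other lists that passed on the number of regions.

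Il4ra, the receptor chain for Il4, had 10 shared regions, Il4 had 9, and Il5 and Pparg, a nuclear receptor active in Th2 cells, had 8 each. Il10, Il13, Il24 and Stat6, the transcription factor activated by the Il4 receptor, had 7 each. The chemokine receptor gene Ccr4 and the repressor gene Gfi1 had 6 each, and Ccr8, also a chemokine receptor gene, and Gata3, the lineage-defining transcription factor, had 5 each. Bhlhe41 and Il1rl1 had 4 each, Ptgdr2 had 3, and Areg, Maf and Rnf128 had 2 each. Windows of neighbouring genes overlap, so Il4 and Il13 shared some regions. Windows also take in regions of other genes, such as the Rad50 promoter in the Il5 window. The random lists were matched on gene length alone, and not on such clustering or on gene density.

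The Gata3 promoter region on chromosome 2 at 9878052 to 9879965 had fold enrichments of 5.59 and 6.53. A stronger region lay 5′ of it at 9888908 to 9890052 with 10.2 and 10.9, and introns 2, 3 and 4 held regions of 2.25 and 2.41, 2.63 and 3.67, and 4.27 and 5.57. Promoter fold enrichments were 7.31 and 9.13 at Maf, a transcription factor of the Il4 promoter, 6.65 and 7.33 at Stat6, 4.75 and 4.88 at Il4ra, and 10.3 and 10.2 at Pparg. They were 6.04 and 7.51 at Ccr4, 8.11 and 7.85 at Ccr8, 5.63 and 7.17 at Gfi1, and 6.12 and 5.98 at Il24. They were 6.44 and 5.99 at Bhlhe41, 8.72 and 7.54 at Areg, and 10.02 and 12.3 at Rnf128. Il10 lacked a promoter region, and its strongest region lay 18.6 kb downstream of the start site on chromosome 1 at 131038040 to 131038808, with 11.1 and 11.5. The strongest intergenic region in the Il1rl1 window lay 16.3 kb upstream on chromosome 1 at 40412602 to 40413978, with 11.1 and 10.7.

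The follicular helper list had promoter regions at 10 of 10 genes (Fisher's exact test, adjusted p = 0.0182) and the regulatory list at 10 of 12 (adjusted p = 0.105). The Th1 list had them at 12 of 15 (adjusted p = 0.123) and the Th17 list at 5 of 14 (adjusted p = 0.121, exact tests against other genes). Among regions with −log10 q of at least 10 the follicular share was 80% and the call was lost (exact test, adjusted p = 0.127), while the regulatory list at 83.3% (adjusted p = 0.0486) and the Th17 list at 21.4% (adjusted p = 0.0426) passed. The 4 lists were not tested against one another. The median number of shared regions was 6.5 for the regulatory list (adjusted p = 0.0017), 5.5 for the follicular list (adjusted p = 0.0136), 4 for Th17 (adjusted p = 0.174) and 3 for Th1 (adjusted p = 1, permutation tests). With 100 kb on each side the follicular call was lost (permutation test, adjusted p = 0.118). Set directly against these lists, the Th2 median of 6 regions passed the test against none. The difference was 3 regions against Th1 (permutation p = 0.0730, adjusted p = 0.292) and 2 against Th17 (p = 0.209, adjusted p = 0.418). It was -0.5 against the regulatory list and 0.5 against the follicular list (permutation test, adjusted p = 0.966 for both). These tests treat genes as units within 1 group, and genes are not independent replicates. In the simulation the test between lists passed for 0% of 100 random pairs, and no true difference was planted. Differences between these lists could therefore have been missed.

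In the Th1 list, Stat4, Il12rb2 and Runx3 had the most shared regions, with 11, 9 and 9. Tbx21, which encodes the Th1 regulator T-bet, had 5 regions and a promoter region on chromosome 11 at 97114402 to 97115427 with 4.62 and 6.46, covering exon 1. Ifng, the signature Th1 cytokine, and Xcl1 had 0 shared regions in their windows, and Ccl5 had 2 but none at its promoter. In the Th17 list, Rora had 19 regions and Il1r1 and Ltb4r1 had 7 each, the last 2 without a promoter region. The cytokine gene Il22 and the chemokine gene Ccl20 had 0. Il17a and Il17f had 2 and 4 regions, none at a promoter. In the regulatory list, Il2ra had 19, Nrp1 14 and Ctla4 9 regions, while Itgb8 had 1 and Lrrc32 had 3. Foxp3, the regulatory T cell factor, and Itgae had 7 regions each, none within 1 kb of their protein-coding start sites. In the Foxp3 window 1 region, in exon 14, was nearest the start of Foxp3, and the others were nearest those of Ppp1r3f or Ccdc22. In the follicular list, Cxcr5 had 11, Sh2d1a 8 and Tox2 7, and the fewest were 1 at Ascl2 and 3 at Pou2af1.

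Genes of general T cell identity and activation had open promoters almost throughout. All 17 pan-T cell genes had a promoter region (exact test, adjusted p = 0.00174) and a median of 8 shared regions against 3 in random lists (permutation test, adjusted p = 0.00068). Bcl11b had 13 regions and Cd6 12, and Zap70 and Lat, which carry the antigen receptor signal, had 3 and 6. All 17 genes of the antigen receptor, AP-1, NFAT and NF-κB list (exact test, adjusted p = 0.00174) and all 15 of the JAK and STAT list (adjusted p = 0.0019) had one. Their median numbers of regions were 5 (permutation test, adjusted p = 0.0355) and 8 (adjusted p = 0.00068), and the first call was lost with the gene body alone (adjusted p = 0.101). In these lists Prkcq had 23 regions, Nfatc2 16 and Nfkb1 15, and Jak1 had 18, Stat5b 13, and Cish and Stat5a 10 each. The fewest were 2 at Jun and 3 at Fosl2 and Nfkbia, and 3 at Il2rg and 4 at Socs2.

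The activation list had promoter regions at 16 of 18 genes (exact test, adjusted p = 0.0182) and a median of 8.5 regions (permutation test, adjusted p = 0.00068). Irf4 had 11, and Egr3, Lta and Tnfrsf9 had 10 each. Il2, the T cell growth factor gene, had 3, and Il3, with 4, and Cd40lg, with 7, lacked a promoter region. The naive and memory list had them at 11 of 12 genes (exact test, adjusted p = 0.0345) and a median of 8 regions (permutation test, adjusted p = 0.00068). Its promoter call was lost with replicate 1 alone (exact test, adjusted p = 0.0566) and with promoters of 2.5 kb (adjusted p = 0.0543). Bach2, a repressor that restrains effector differentiation, had 43 regions, Foxp1 40 and Lef1 17. S1pr1 had 3. All 14 housekeeping genes had one (exact test, adjusted p = 0.00205), with a median of 4.5 regions (permutation test, adjusted p = 0.0121), a call lost with replicate 2 alone (adjusted p = 0.0846) and with −log10 q of at least 10 (adjusted p = 0.113). Actb had 7 regions and Ywhaz 6, Gapdh, Ppia and Sdha had 3 each and Hprt had 2.

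Marker genes of 3 of 6 lists of other cell types had open promoters less often than other genes. The shares were 2 of 11 for CD8 T and natural killer cells (exact test, adjusted p = 0.0234), 3 of 13 for myeloid cells (adjusted p = 0.0345) and 3 of 18 for non-haematopoietic tissues (adjusted p = 0.0019). For B cells 3 of 12 (exact test, adjusted p = 0.0505), for mast cells and basophils 2 of 9 (adjusted p = 0.0528) and for erythroid cells and megakaryocytes 4 of 10 (adjusted p = 0.338) did not pass. With promoters of 2.5 kb the calls were lost for CD8 T and natural killer cells at 36.4% (exact test, adjusted p = 0.152), myeloid cells at 30.8% (adjusted p = 0.0610) and non-haematopoietic tissues at 38.9% (adjusted p = 0.116). The CD8 T and natural killer call was also lost with the gene's 5′ end alone (exact test, adjusted p = 0.0917). With −log10 q of at least 10, B cells at 16.7% and mast cells and basophils at 11.1% passed (exact test, adjusted p = 0.0288 each). B cells also passed with promoters of 2.5 kb (exact test, adjusted p = 0.0344), and mast cells and basophils with replicate 2 alone (adjusted p = 0.0493). None of these 6 lists passed the test against random lists in the number of regions per gene. Their medians were 2 for CD8 T and natural killer cells, B cells and erythroid cells (permutation test, adjusted p = 1 each), 1 for myeloid cells (adjusted p = 0.533), 0 for mast cells and basophils (adjusted p = 0.175) and 1 for non-haematopoietic tissues (adjusted p = 0.312).

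Cd8a, the killer cell receptor genes Klrk1 and Ncr1, and the perforin gene Prf1 had 0 shared regions, whereas Gzmk had 9 and Klrb1c 7. The promoter regions of that list were at Klre1 and Cd8b1. The B cell gene Ms4a1 had 0, Ebf1 had 12, Cd79a 6 and Vpreb3 5, and Cd22, Cd79b, Cr2, Fcer2a and Fcrla had 2 each. Promoter regions were present at Ebf1, with 9.45 and 10.5, Blnk and Cr2. The myeloid genes Lyz2, Adgre1 and S100a8 had 0, and Itgam had 7, Fcgr3 6 and Elane 5. The mast cell genes Cpa3, Fcer1a, Mcpt4, Mcpt8 and Tpsb2 had 0, and Hdc had 5, Cd200r3 4 and Ms4a2 2. The erythroid genes Gp9 and Rhag had 0, Itga2b had 5 and Klf1 4, and Epor, Gata1, Hba-a1 and Pf4 had 2 each. Of the non-haematopoietic genes, Col3a1, Krt14, Krt5, Nanog, Olig2 and Ttr had 0, and Cdh5, Gfap, Pou5f1 and Syn1 had 3 each.

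**Figure D2:**
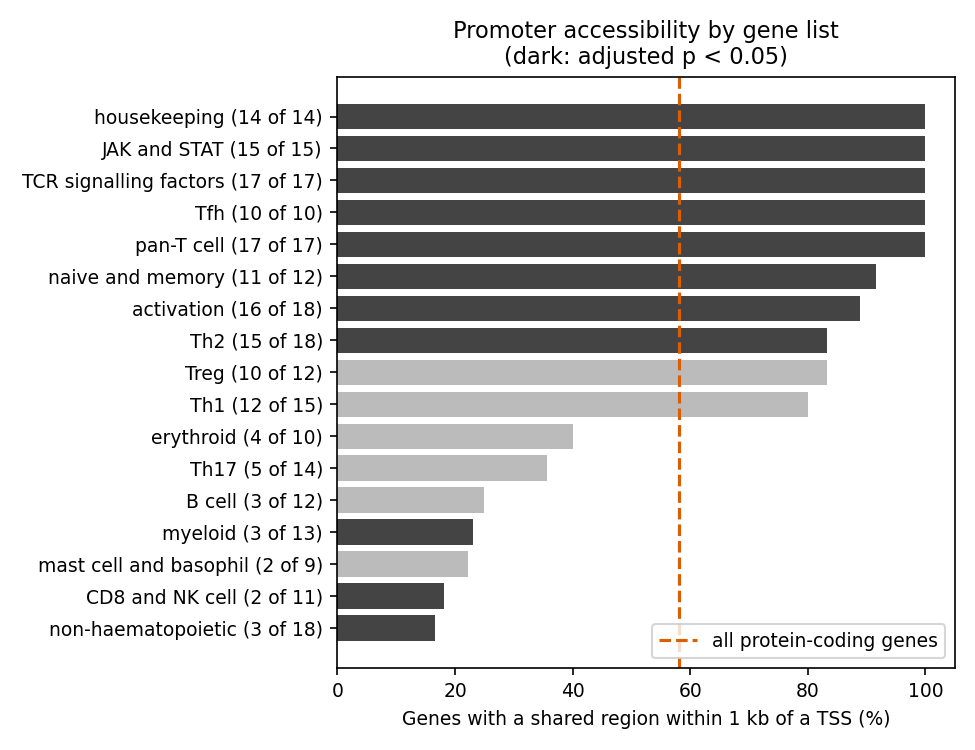
Share of genes in each of the 17 lists with a shared open region within 1 kb of a transcription start site (x axis, %), with the counts beside each name and a dashed line at the 58.1% of all protein-coding genes. Dark bars mark lists with an adjusted p under 0.05 (Fisher's exact test); 5 lists reached 100%, and the lowest share was 16.7%, for non-haematopoietic genes.

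The replicates shared most of their open regions, and the strong regions almost without exception. Of replicate 1's regions, 44695 (86.7%, 95% Wilson interval 86.4 to 87.0) overlapped a region of replicate 2 by at least 1 bp. Of replicate 2's regions, 44756 (73.5%, 73.1 to 73.9) overlapped one of replicate 1. With one list shifted at random along each chromosome, 3.10% and 2.64% overlapped (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). The overlaps merged into 44136 shared regions, and the Jaccard index of covered bases was 0.648. Among the weakest 10% of regions by fold enrichment, 50.01% of replicate 1 and 29.3% of replicate 2 were shared, and among the strongest 10%, 99.98% and 99.97%. Across shared regions, which are not independent replicates, fold enrichment had a Spearman rho of 0.879 between replicates. The median ratio of replicate 2 to replicate 1 was 1.11, with 5th and 95th percentiles of 0.760 and 1.64. The summits of a shared region lay a median of 32 bp apart.

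**Figure D3:**
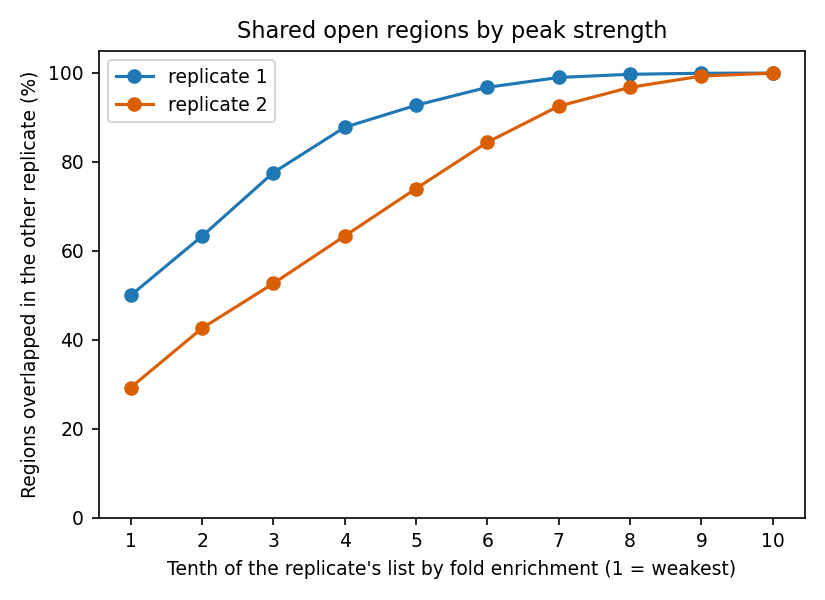
Share of open regions of each replicate that overlapped a region of the other (y axis, %), by decile of fold enrichment within that replicate's own list (x axis, 1 is the weakest). Points are single values per replicate, rising from 50.01% to 99.98% in replicate 1 and from 29.3% to 99.97% in replicate 2.

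Regions found in 1 replicate were weaker and narrower than shared ones. In replicate 1 the median fold enrichment was 6.16 for shared and 3.33 for unshared regions, with median widths of 605 and 259 bp. In replicate 2 it was 7.002 and 3.61, with widths of 655 and 263 bp. The ratios of the medians were 1.85 and 1.94. With −log10 p in place of fold enrichment, which is on another scale, the mean ratio over both replicates was 3.85. The 6862 regions of replicate 1 alone were led by a region on chromosome 1 at 122357130 to 122357309, 789 kb from the Ddx18 start site, with 16.4. Intergenic regions nearest Adamts20 and Cdyl had 10.5 and 10.3, and regions in Cacna1e intron 3 and Nxpe4 intron 2 had 9.49 and 9.01. The 16135 regions of replicate 2 alone were led by a region on chromosome 4 at 28176838 to 28177038, 636 kb from Epha7, with 14.2. It was followed by regions within the span of Fyb, an adaptor gene of T cells, with 13.6, in Tex14 intron 3 with 12.2, and nearest Tcf4 and 1600014C23Rik with 11.8 each.

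Promoters were over-represented among the shared regions. By their centres, 12103 (27.5%) lay within 1 kb of a start site of a protein-coding gene, a class that makes up 2.03% of the genome, a ratio of 13.5. Exons held 3.16% (ratio 1.34), introns 36.3% (ratio 1.02) and intergenic sequence 33.0% (ratio 0.550). Of the regions seen in 1 replicate alone, 6.14% of replicate 1's and 4.66% of replicate 2's lay at promoters. Of 21938 protein-coding genes, 12750 (58.1%) had a promoter region in both replicates, 717 (3.27%) in 1 and 8471 (38.6%) in neither. Counted by any overlap, the 12538 shared regions at promoters had median fold enrichments of 9.10 and 10.2 and a median width of 1154 bp. The 31598 elsewhere had 5.51 and 6.30, with 620 bp.

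Of the consensus sequences over-represented at the summits of shared regions, CTCF was second in odds ratio to NRF1 against flanks and had the highest against windows matched on G and C content. Consensus sequences were counted in 200 bp windows at summits and in windows 1 kb away, and odds ratios are given for replicate 1 and then replicate 2. The CTCF consensus was in 5.28% and 5.42% of summit windows, against 0.268% and 0.258% of flanks, with odds ratios of 20.6 (95% interval 16.98 to 25.1) and 22.0 (18.1 to 26.9). NRF1 was in 0.468% and 0.488%, against 3 and 2 flank windows, with odds ratios of 52.7 (18.3 to 152) and 76.99 (22.1 to 268). CRE had 10.6 and 10.8, and SP/KLF had 10.2 and 9.88. The consensus of AP-1, the dimer of Fos, Jun and Batf proteins, was in 17.6% and 18.3%, against 3.05% and 3.06%, with odds ratios of 6.81 (6.40 to 7.25) and 7.10 (6.67 to 7.56). The composite elements that join an AP-1 site to an IRF site, bound by Batf and Irf4 in T cells, had odds ratios of 11.4 and 9.74 in the adjacent and 9.48 and 8.04 in the spaced form. The MAF site next to AP-1, whose consensus contains the whole AP-1 consensus, had 6.06 and 6.51, below AP-1 alone. The AP-1 and IRF composites also contain an AP-1 core, so none of these ratios is independent of that of AP-1. ETS had 5.30 and 5.54, STAT with a spacer of 3 bases 2.54 and 2.52, STAT with 4 bases, the spacing preferred by Stat6, 1.20 and 1.16, and RUNX 1.54 and 1.53. The call of STAT with 4 bases was lost in 100 bp windows (exact test, adjusted p = 0.0855) and with −log10 q of at least 10 (adjusted p = 0.0610). It was kept against windows matched on G and C content (exact test, adjusted p = 4.1e-11 and 2.4e-10).

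Of 30 consensus sequences, 20 were higher at summits than in flanks in both replicates and 7 were lower (Fisher's exact test, two-sided, adjusted over 30 in each replicate). The 20 count AP-1 and each composite that contains its core separately. The short GATA consensus was lower, with odds ratios of 0.726 (95% interval 0.704 to 0.749) and 0.712 (0.690 to 0.734), as was NFAT with 0.552 and 0.548, GFI1 with 0.521 and 0.509, and FOX with 0.726 and 0.707. The longer GATA consensus was higher, with 1.35 and 1.31. Summit windows were 52.9% and 53.0% G and C, against 44.7% in flanks of both replicates. Against random windows matched on G and C content, the direction of the short GATA consensus turned, to 1.12 and 1.11, and so did FOX, to 1.13 (exact test, adjusted p = 0.0229) and 1.10 (adjusted p = 0.0619), and MEF2, from 0.700 and 0.771 to 1.58 and 1.74. NFAT was at 0.795 and 0.824, and GFI1, at 0.784 (exact test, adjusted p = 0.0516) and 0.776 (adjusted p = 0.0399), no longer passed in both replicates. Set against its reversed sequence, NFAT lost its call at a mean ratio of 0.965, as did FOX at 0.995, while GATA turned at 1.20. GFI1 kept its call there, with its reversed sequence at 1.21 and 1.41. With matched windows CTCF was at 17.4 and 18.5, the adjacent AP-1 and IRF composite at 11.1 and 13.3, the spaced one at 13.2 and 11.8, AP-1 at 7.49 and 7.53, and CRE at 7.08 and 7.26. In the same windows SP/KLF fell from 10.2 and 9.88 to 2.86 and 2.82, NRF1 from 52.7 and 76.99 to 10.03 and 11.6, and NF-κB from 2.28 and 2.37 to 1.23 and 1.19. ISRE went from 1.56 and 1.498 to 2.37 and 2.40, CEBP from 2.75 and 2.88 to 4.76 and 4.43. The E-box of E-proteins lost its call, at 0.992 and 1.00 from 1.35 and 1.37.

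**Figure D4:**
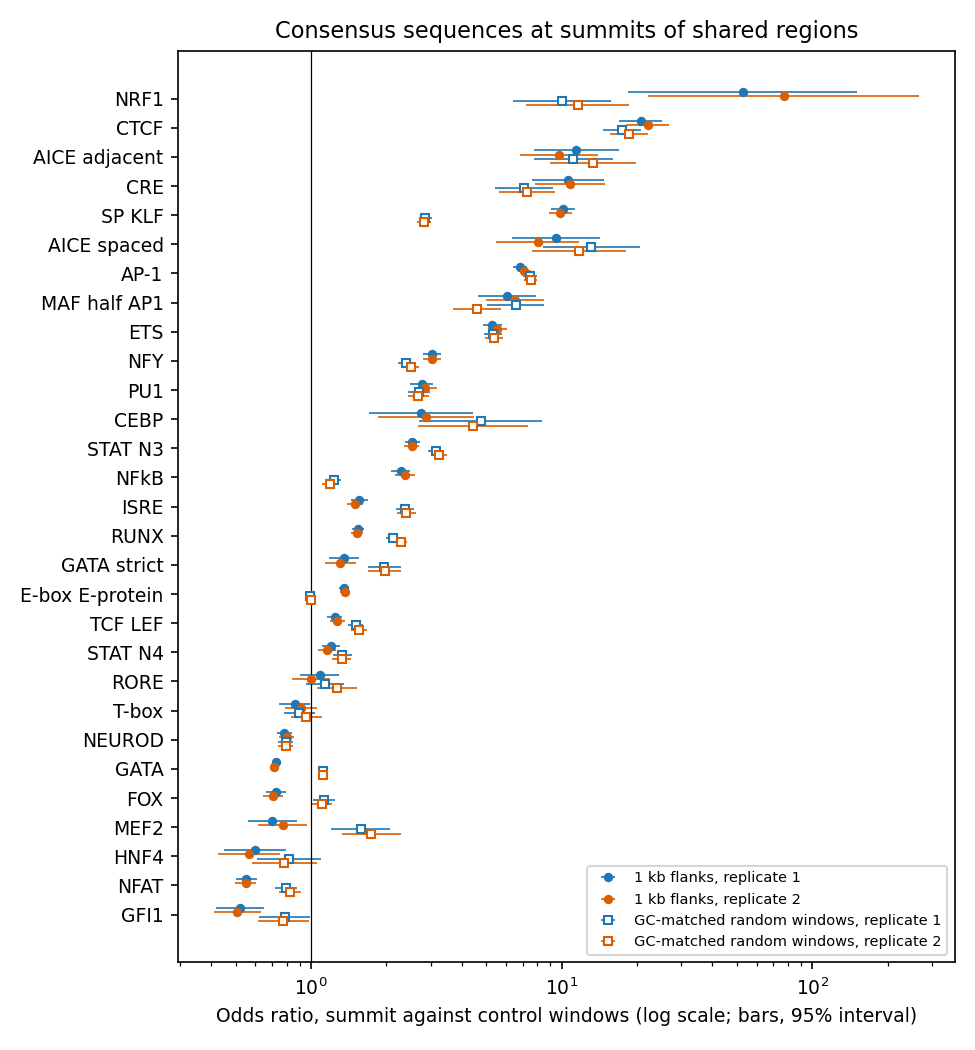
Odds ratios of consensus sequences in 200 bp summit windows against control windows (x axis, log scale), with bars for the 95% interval. Filled circles use windows 1 kb away, open squares random windows matched on G and C content, and colours mark the replicate; HNF1, present in 1 summit window per replicate, is not drawn. CTCF lay at 20.6 and 22.0 and AP-1 at 6.81 and 7.10 against flanks.

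Promoters and other open regions carried different sequences. AP-1 was in 23.3% and 24.2% of summit windows away from promoters and in 3.46% and 3.64% at promoters, with odds ratios of 8.45 (95% interval 7.65 to 9.33) and 8.42 (7.64 to 9.27). The short GATA consensus was in 30.7% and 30.3% away from promoters and in 9.58% and 9.37% at them, with odds ratios of 4.17 and 4.21. RUNX had 4.20 and 4.21, CTCF 4.58 and 4.72, STAT with a spacer of 3 bases 3.31 and 3.09, and NFAT 2.80 and 2.56. SP/KLF went the other way, with 2.32% and 2.30% away from promoters and 24.3% and 24.96% at them, as did NFY with odds ratios of 0.190 and 0.195, NRF1 with 0.0678 and 0.0720, CRE with 0.152 and 0.161, and ETS with 0.801 and 0.821. The ETS call was lost in 100 bp windows, at a mean of 0.911 (exact test, adjusted p = 0.107). In all, 21 sequences were higher away from promoters in both replicates and 6 were higher at promoters (Fisher's exact test, two-sided, adjusted over 30). Windows at promoters were 64.5% and 64.6% G and C, and the others 48.3% and 48.4%. No comparison matched on G and C content was made between them. Base content can therefore not be told apart from other sources of these ratios and counts.

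Non-promoter regions stitched with their neighbours formed 18970 clusters, of which 65 held 10 or more regions. The cluster ranked highest by summed fold enrichment in both replicates spanned Clec16a, beside Socs1, on chromosome 16 at 10655182 to 10781683, with 25 regions over 127 kb and sums of 131 and 143. Clusters at Chd2, a chromatin remodeller, with 18 regions, Bach2 with 21, and Irf4 and Exoc2 with 22 followed. Irf4 is required for Th2 differentiation. Next were Atxn1 with 20, Id3 and E2f2 with 19, and Sh2d4b, Tspan14 and Fam213a with 16. Intergenic clusters lay 114 kb from Olig3 with 13 regions and 63.7 kb from Tomm20 with 16. Prkcq, a kinase of the antigen receptor pathway, and Glb1 with Ccr4 held 15 each. Rnf157 held 12, Ubac2 with Timm8a2 18, Ppt1 with Cap1 13, and the cluster of Gimap8, Gimap9, Gimap4, Gimap6, Gimap7, Gimap1 and Gm28053, mostly GTPases of lymphocyte survival, 17. With a stitching distance of 5 kb, 2 of these 15 clusters were still among the first 15, and among regions with −log10 q of at least 10, 6 were.

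The strongest promoter regions were at 2310009B15Rik on chromosome 1, with fold enrichments of 22.4 and 25.4, at 5430403G16Rik with 18.96 and 21.9, and at Golph3l with 18.6 and 21.4. They were followed by Abhd18 with 19.002 and 20.3, Kifc1 with 18.1 and 19.7, Zfp617 with 18.1 and 19.7, Pigf with 17.8 and 19.8, Bbs9 with 18.1 and 19.4, Tmem218 with 17.8 and 19.6, and Slc25a44 with 18.3 and 19.2. The strongest regions away from promoters had higher values. The highest lay in Cntnap5b intron 10 on chromosome 1 at 100180105 to 100180426, with 41.6 and 43.97, and in Lars2 exon 21 on chromosome 9 at 123461798 to 123462187, with 40.7 and 42.6. Gphn intron 2 followed with 34.4 and 38.4, and Jarid2 intron 3 ended the first 10 with 23.7 and 26.1. The others lay outside protein-coding genes, the only genes used. They were nearest Myl12b with 32.9 and 36.6, 4930467E23Rik with 32.5 and 34.8, Arhgef26 with 31.4 and 34.0, Col19a1 with 28.6 and 33.4, Esp38 with 28.3 and 31.2, and Gm8797 with 26.2 and 27.3. In 8 of these 10 regions, and in 2 of the 10 promoter regions, the median 25 base word occurred at more than 1 place in the reference.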

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

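Signal was also present in sequence that the annotation-based comparisons did not use. Replicate 1 had 97 regions and replicate 2 had 104 on unplaced or unlocalized scaffolds, above the limit of 3 that a count of 0 allows. Including 2 and 3 regions on the mitochondrial chromosome, 89 of 99 and 89 of 107 were shared between replicates. Their median fold enrichment was 4.43 and 4.30, against 5.58 and 5.65 on the main chromosomes, but 8 and 10 of them lay in the top 1% of fold enrichment, with highest values of 38.2 and 40.5.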

How the results depend on the processing

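Of 519 recalculations of 112 results, all under alternatives fixed in advance, 426 kept their direction and side of the threshold or their size, 34 lost a call, 9 gained one, 28 turned and 22 moved in size. The overlap of the replicates passed its test in its 12 recalculations, of which those on merging changed nothing, since gaps were at least 152 bp. With −log10 q of at least 10, the Spearman rho of fold enrichment was 0.875, the ratio of shared to unshared strength 1.48, the promoter share of regions 37.0%, the share of promoters open 51.8% and the number of leading clusters kept 6 of 15. The rho was 0.894 with reciprocal overlap, 0.897 with −log10 p and 0.876 with lists of equal length. The strength ratio with −log10 p was 3.85, on another scale than that of fold enrichment. Promoters of 2.5 kb gave 31.4% of regions and 60.6% of genes, and the gene's 5′ end alone 24.2% and 55.9%. With each replicate alone the promoter share of regions ranged from 21.4% to 24.6%, the share of genes from 59.4% to 60.1%, and the clusters kept from 8 to 11, and a stitching distance of 5 kb kept 2. The promoter share of the Th2 list ranged from 83.3% to 88.9% with each replicate alone, and the call was lost without replicate 2 and, at 72.2%, with the 5′ end alone.

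With the strongest region's rank in place of the number of regions, the 9 lists that passed fell to 0, and the Th2 list was at rank 80.6, regulatory 75.4, follicular 67.4 and pan-T cell 72.8, the last 3 below random lists. The Th2 difference was then -0.905 against Th1, -6.43 against Th17 and 5.17 against the regulatory list, and with the gene body alone it was -2 against the follicular list. None of these passed. Among lists near the random median, direction turned with 100 kb windows for CD8 and natural killer (8 regions), B cell (10) and myeloid genes (8). It turned for B cell genes without replicate 2 (range 2 to 3) and with the stricter q (2), and for erythroid genes with each replicate alone (2 and 2), the stricter q (1) and the gene body (0), none past its threshold.

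Of consensus sequences, 7 were lower at summits, and 2 of these stayed lower with controls matched on G and C content. Against reversed sequences 3 were lower, namely GFI1, HNF4 and the E-box. Reversed HNF4 was itself over-represented at summits, at 1.81 and 1.62, so that comparison adds no evidence about HNF4. Reversed GFI1 was present in only 37 and 43 summit windows. The E-box was not among the 7, since it was higher at summits than in flanks. Mean odds ratios that turned were, with matched controls, GATA 1.11, FOX 1.11, MEF2 1.66 and E-box 0.998, and against reversed sequences GATA 1.20, T-box 1.13 and, with a reversed sequence itself over-represented at summits and so no evidence of a turn, SP/KLF 0.942 (reversed sequence 10.7 and 10.6), TCF/LEF 0.889 (1.39 and 1.44) and E-box 0.718 (1.80 and 1.99). In 100 bp windows RORE was 0.979. The values there of 0.905 for HNF1, and 0.398 away from promoters, are ratios of window numbers, since HNF1 had 0 matches. Matched base content is the construction of the first; otherwise the cause was not tested. No paired analysis was possible because there is 1 group. What depth limits was not tested, apart from the number of regions. The lowest summit pileups were 9 and 10 counts.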

Other observations

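The gene families and the promoter comparison of the Th2 list with other helper lists in this part were chosen only after the data were seen. So were the tests of other blood cells, thinned pileups, regions per marker gene, repeated words against promoters and the single region near Col19a1. Receptor and structural gene families of other tissues seldom had open promoters. Shared promoter regions were present at 17 of 1135 olfactory receptor genes (Olfr, 1.498%), 2 of 331 vomeronasal receptor genes (Vmn), 2 of 110 keratin genes (Krt) and 1 of 42 beta-defensin genes (Defb). Cytochrome P450 genes (Cyp) had them at 20 of 100, ion channel genes of the Scn and Kcn families at 42 of 99 (Fisher's exact test, adjusted p = 0.00306), and Hox genes at 14 of 39 (adjusted p = 0.0069). Chemokine genes of the Ccl and Cxcl families had them at 8 of 35 (exact test, adjusted p = 6.8e-05), whereas their receptors of the Ccr and Cxcr families had them at 13 of 19 (adjusted p = 0.487). The difference between chemokines and receptors was not tested.

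Families that most cells use were open at their promoters: 76 of 79 ribosomal protein genes (Rpl and Rps), 78 of 78 mitochondrial ribosomal protein genes, 38 of 40 proteasome genes (Psm) and 45 of 46 Nduf genes of respiratory complex I. Zinc finger genes named Zfp had promoter regions at 317 of 394 and histone genes of the Hist1 group at 46 of 54 (exact test, adjusted p = 4.6e-05). Among immune families, all 12 Irf genes (exact test, adjusted p = 0.00306), all 8 Gimap genes (adjusted p = 0.0285), 18 of 20 Tnfrsf genes (adjusted p = 0.0039) and 21 of 24 Dusp phosphatase genes (adjusted p = 0.004) had one. All 7 Stat genes and all 5 Ikzf genes had one without passing (adjusted p = 0.0515 and 0.0831, Fisher's exact test over 21 families). Th2 promoters were open more often than those of the Th17 list (15 of 18 against 5 of 14, Fisher's exact test p = 0.0100, adjusted p = 0.0400), and the tests against the Th1, regulatory and follicular lists, of 10 to 15 genes, did not pass (adjusted p = 1 each).

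Of the 25 widest shared regions, 14 began within the first 3.3 Mb of a chromosome, where 78 of all shared regions lay. None of these 14 began before position 3000010. The widest spanned 17174 bp on chromosome 9 from 3000010 to 3017183. Promoters of Ubtf (4361 bp), Ccnd2 (4188 bp) and Brd2 (4171 bp) were also among them. Chromosome X had 7.22 and 8.19 regions per Mb, against autosomal medians of 19.5 and 23.4 and a highest value of 32.1 and 37.5. Chromosome Y had 7 and 9 regions, and 4 shared regions lay on it. The sex of the cells, which the labels do not state, was not tested.

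Replicate 2 held more regions than replicate 1, by a ratio of 1.18. Its background coverage was also higher, by 1.18, so deeper coverage was tested by dividing pileup and background of the 16135 regions of replicate 2 alone by that ratio. After that 3.11% lay under the weakest p in replicate 1's list. Thinning the summit pileups of replicate 2's regions at random by the same ratio left 59989 regions (SD 25.9, counting error only), against 51557 in replicate 1. Lower summit counts alone therefore did not bring replicate 2 down to replicate 1's number. Both steps used only the summits of regions already called, and not the width that a call may need. The narrowest regions were 170 bp in replicate 1 and 151 bp in replicate 2. Coverage can therefore not be excluded as the source of the number of regions. A Poisson redraw of every scaled pileup of replicate 2 put 4.81% of its regions, and 12.9% of those in replicate 2 alone, under that p, against 26.5% not found in replicate 1. These pileups were selected by being called, which understates the redrawn shares, so counting noise cannot be told apart from other spread between libraries, and no biological explanation was tested, since both libraries belong to 1 group.

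The strongest regions away from promoters had higher fold enrichments than the strongest promoters, and repeated sequence was tested as a technical explanation. The median 25 base word of the 10 regions occurred at 3 places in the reference, over 1 in the 10 promoter regions but under the 10 places set in advance, so this explanation cannot be told apart from others. The median word was repeated in 8 of 10 regions against 2 of 10 at promoters (Fisher's exact test, p = 0.0230). Copies absent from the reference were not counted. Of the 10 regions, 1 shared words with the mitochondrial chromosome, which argues against mitochondrial sequence copied into the nucleus for the set. In that region, nearest Col19a1 on chromosome 1 at 24612468 to 24613540, 96.0% of the words also occur on the mitochondrial chromosome, so reads from mitochondria are a candidate source of its signal.

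Open regions were present around marker genes of other cell types, in windows of 6 lists. Of 151 such regions, 46 (30.5%) lay at the promoter of another gene or held the CTCF consensus, against 88 of 776 (11.3%) around genes of 8 T cell lists (odds ratio 3.43, Fisher's exact test p = 1.9e-08). Per gene such regions were not more frequent, at 0.630 over 73 genes against 0.759 over 116, so the share reflects the larger number of other regions around T cell genes and leaves neighbouring promoters and CTCF sites open as an explanation. Other blood cells among the Th2 cells stay open as an explanation, which the data cannot decide. Of their markers, 10 of 45 genes of 4 such lists (22.2%) had a promoter region, against 58.2% of other genes (Fisher's exact test, p = 1.1e-06). A small share of such cells would not raise this to the level of other genes, so the comparison does not exclude them.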
